A study of Mus musculus with 4 samples.

How the data were processed

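Whole-genome bisulfite sequencing measured cytosine methylation in 4 libraries of genomic DNA from spleen CD4+ T cells of NOD mice, a strain that develops autoimmune diabetes spontaneously. Per the labels, the mice received PBS or a combination of OX40L and Jagged-1 proteins weekly from the age of 6 weeks for 3 weeks, and cells were taken 1 week after the last dose, at 10 weeks. Flow sorting separated CD4+CD25- effector T cells (Teff) from CD4+CD25hi regulatory T cells (Treg). The groups were PBS Teff, PBS Treg, OX40L-JAG1 Teff and OX40L-JAG1 Treg, with 1 library each. The labels do not say how many animals a library came from. Libraries were made with a Kapa Hyper kit and converted with a Zymo Lightning EZ kit, per the labels' protocols.

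Trimmomatic and Bismark, with the mouse build mm10, were used by the authors, per the submitters' processing notes; versions, settings and duplicate removal were not given in the sources used here. The deposited table lists 25374149 cytosine positions with the strands on separate lines. Per the file headers, it gives for each library the count of reads at a position, the count of methylated reads, and a methylation level. The deposited levels are headed as percentages but run as a fraction from 0 to 1, and equal methylated reads over reads to 6 decimals. Every nonzero count in the deposited table is at least 5, so positions with fewer reads in a library are listed at 0. Totals of the table therefore hold only positions at or above that minimum, and are not the sequencing depth of a library.

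The listed reads numbered 208402911 for PBS Teff, 131555634 for PBS Treg, 159291553 for OX40L-JAG1 Teff and 103584075 for OX40L-JAG1 Treg. Positions with at least 5 reads in all 4 libraries were kept, 4795507 in number, or 18.9% of the table. Levels of whole libraries were taken over these positions, without the mitochondrial genome. Methylated and total reads were then summed in fixed, non-overlapping windows of 1 kb, and the 314531 windows with at least 5 kept positions were tested. These windows hold 44.8% of the kept positions and cover 315 Mb. A window held a median of 115 reads in PBS Teff, 85 in PBS Treg, 92 in OX40L-JAG1 Teff and 71 in OX40L-JAG1 Treg. Read numbers of a library, a window or a gene are sums over positions, in which a read counts once at each position it covers. Fewer DNA molecules may therefore lie behind them.

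Each comparison of 2 libraries used the two-sided Fisher's exact test on methylated and unmethylated reads per window with Benjamini-Hochberg adjustment over all windows. A window was called at an adjusted p under 0.05 with a difference of at least 20 percentage points. With 1 library per group these tests compare libraries and not conditions, and no p-value for a cell type or a treatment is given. Treg was compared with Teff in the PBS pair and in the OX40L-JAG1 pair. These pairs share no library, and a window counted as a cell type difference when it was called in the same direction in both. OX40L-JAG1 was compared with PBS in Teff and in Treg. A difference between the cell types in the response was tested with a Wald test of the interaction in a logistic model, with 0.5 added to each cell, and the same thresholds. Intervals are 95% Wilson intervals for levels and 95% Newcombe intervals for differences. They cover counting error only, since neighbouring positions on a read are not independent and duplicate reads may remain.

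Genes were taken from a RefSeq gene table of GRCm38.p6, the assembly that mm10 names. The table gives no strand and no exons, so a window belongs to a gene when it overlaps the gene or the 5 kb on either side, and exon, intron and promoter were not told apart. Planned promoter values were not computed for that reason. Positions are printed as deposited. Named genes followed a rule set before the data were examined. Foxp3 comes before all others. The 10 genes lower and the 10 genes higher in Treg follow, and then the 5 genes each way for the treatment in each cell type, ranked by the interval bound nearest 0, without predicted gene models. Genes of 15 fixed lists with a called window complete the set. Not every gene that the rule selects is described. The lists cover Treg signature, naive and conventional T cell, effector and helper lineage, checkpoint and exhaustion, Notch pathway, OX40 and NF-kB signalling, proliferation, DNA methylation machinery and pan T cell genes. Lists of B cell, CD8 T and NK cell, and myeloid genes stand for other cell types, and imprinted, housekeeping and germline genes are internal references. Each list was set beside 10000 random lists of protein-coding genes of the same size, matched on the number of kept positions in 20 bins. A list percentile describes these libraries only. Random lists held few genes with a called window, so a count of 0 by itself does not set a list apart.

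The tests were tried on simulated reads at the real depths, with 50 windows lowered by each known size. In the PBS Treg and Teff comparison, Fisher's test recovered 22% of drops of 20 points, a size at the threshold itself, 64% of 30 points and 90% of 40 points. In the comparison of the Treg libraries, it recovered 22%, 66% and 76% of drops of these sizes. The simulation took all summed reads of a window as independent, which positions on the same read are not. It therefore does not give the rate of false calls in the measured data. In it, at most 1 unchanged window was called in any comparison. The interaction test recovered 26% of drops of 40 points in a single library and called 0 unchanged windows. Over all simulated windows, the lowered ones included, 3.58% had an unadjusted p under 0.05 by Fisher's exact test in the PBS pair. Among the measured windows the share was 5.73%. Alternatives changed the coverage minimum, the window size, the difference required, the read depth, the centring of differences, the weight of reads and the chromosomes used, and limma was fitted over all 4 libraries. A limit of 50 reads per position and coverage in the compared pair only were added after the data were examined. The comparison of how far each cell type moved, in the closing section, was set as a difference of movements and not as their ratio after the values were seen, because the Treg movement was below 0. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1.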

Results

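Methylation was measured in 4 bisulfite libraries that crossed cell type, Teff or Treg, with treatment, PBS or OX40L-JAG1. OX40L is the ligand of the costimulatory receptor OX40, and Jagged-1 is a ligand of Notch receptors. The design asks how methylation differs between Teff and Treg and between PBS and OX40L-JAG1 mice. At the positions read in all libraries, the median number of reads was 14 in PBS Teff, 10 in PBS Treg, 11 in OX40L-JAG1 Teff and 9 in OX40L-JAG1 Treg. Each group was a single library, so no spread between libraries of the same group could be measured. A value given for a gene is that of a single 1-kb window at the gene, and not the level of the whole gene. Values of a whole gene with its flanks are called locus values.

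Methylation over the genome was lower in both OX40L-JAG1 libraries than in the PBS library of the same cell type. Pooled over the shared positions, 85.2% of reads were methylated in PBS Teff and 81.6% in OX40L-JAG1 Teff, a difference of -3.58 points. The values were 84.9% in PBS Treg and 82.2% in OX40L-JAG1 Treg, a difference of -2.74 points. Each Wilson interval was narrower than the first decimal, from 85.197% to 85.210% in PBS Teff for example, and covers counting error only. Treg and Teff lay closer to each other, -0.292 points apart in the PBS pair and 0.547 points apart in the OX40L-JAG1 pair. Positions at 80% or more made up 79.2% of all in PBS Teff, 78.5% in PBS Treg, 70.9% in OX40L-JAG1 Teff and 72.6% in OX40L-JAG1 Treg. The median window difference was below 0 on all 19 autosomes, from -3.07 to -2.31 points in Teff and from -2.38 to -1.71 points in Treg, and it was -3.64 and -2.94 points on the X chromosome. Mitochondrial cytosines, which serve as a reading of incomplete conversion, were called methylated in 0.697%, 0.635%, 0.712% and 0.620% of reads in PBS Teff, PBS Treg, OX40L-JAG1 Teff and OX40L-JAG1 Treg.

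**Figure D1:**
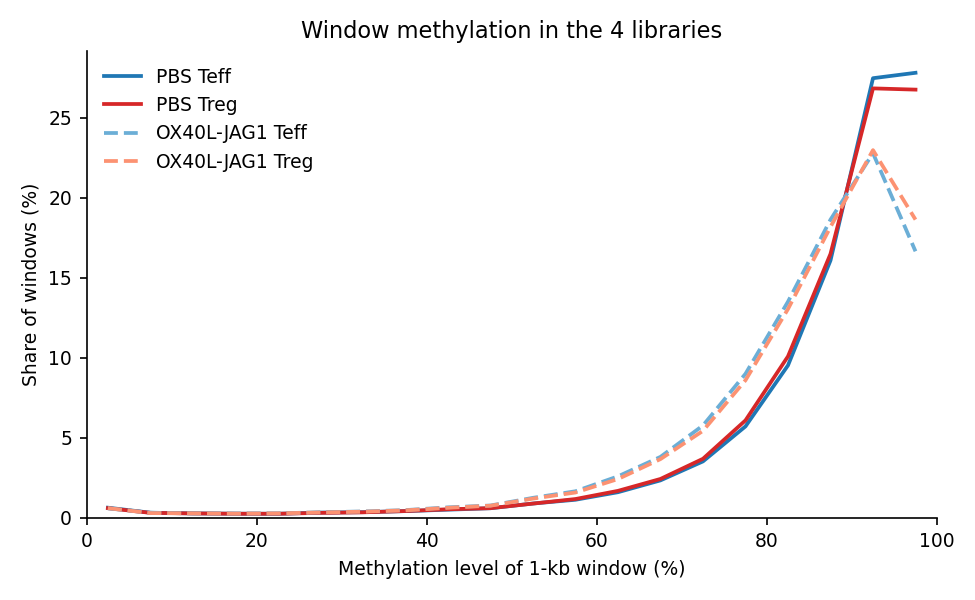
Distribution of methylation over the 314531 windows of 1 kb. The horizontal axis is the level in percent, the vertical axis the share of windows in bins of 5 points, and each line is a library. The OX40L-JAG1 libraries hold fewer windows near full methylation than the PBS libraries, with medians of 87.3% in Teff and 87.8% in Treg against 91.1% and 90.7%.

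Foxp3, the transcription factor that defines the Treg lineage, was less methylated in Treg under both treatments. The gene (RefSeq gene 20371) lies at chromosome X, 7579676 to 7595243, and the window at 7580001 to 7581000 lies in its body. It stood at 94.6% in PBS Teff and 41.0% in PBS Treg, a difference of -53.6 points with an interval from -65.4 to -39.4. In the OX40L-JAG1 pair the levels were 94.3% and 46.5%, a difference of -47.8 points with an interval from -62.2 to -31.1. These rest on 92, 61, 70 and 43 reads, summed over 6 positions, in PBS Teff, PBS Treg, OX40L-JAG1 Teff and OX40L-JAG1 Treg. A read counts at each position it covers, so fewer DNA molecules may lie behind these numbers. The adjusted p was 2.87e-10 in the PBS pair and 2.99e-05 in the OX40L-JAG1 pair by Fisher's exact test. The treatment differences of this window were -0.280 points in Teff and 5.53 points in Treg, neither called. The window at 7578001, beside the gene, was lower in PBS Treg than in PBS Teff by -26.9 points, and its difference of -28.2 points in the OX40L-JAG1 pair missed the threshold at an adjusted p of 0.065 by Fisher's exact test. With 3 windows tested, of which 1 lies in the gene body, most of the Foxp3 gene was not covered in all libraries.

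**Figure D2:**
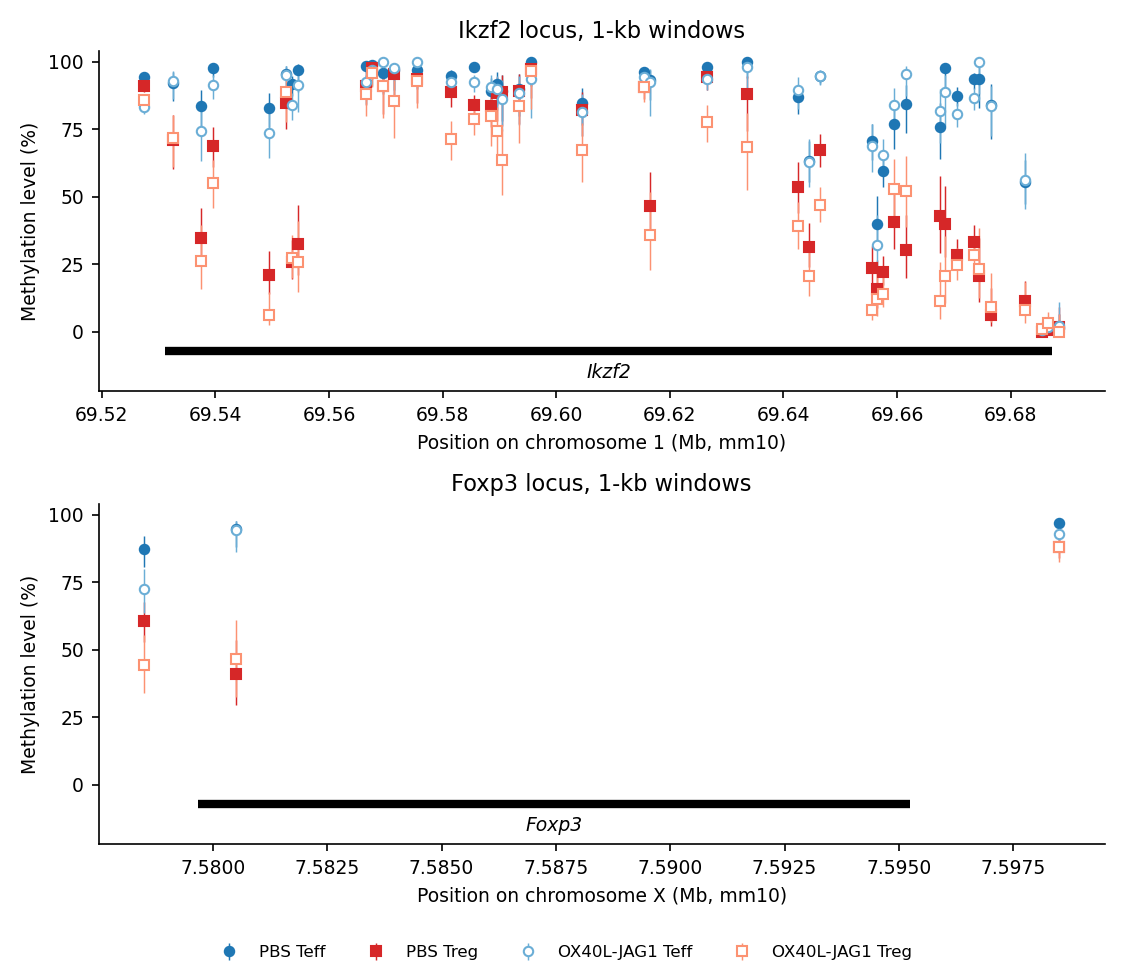
Levels of 1-kb windows along Ikzf2 and Foxp3 in mm10. Horizontal axes give the position in Mb, vertical axes the methylation level in percent, and black bars the genes. Points are libraries and bars are 95% Wilson intervals. Across Ikzf2, 19 of 43 windows are lower in Treg in both pairs.

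Ikzf2 held the most windows of any gene that were lower in Treg. It encodes Helios, a transcription factor of Treg. Of its 43 tested windows, 19 were lower in Treg in both pairs, and 0 were higher in either. The window at chromosome 1, 69676001 to 69677000, stood at 84.0% in PBS Teff and 6.0% in PBS Treg, and at 83.6% in OX40L-JAG1 Teff and 9.3% in OX40L-JAG1 Treg. The differences were -78.0 points with an interval from -86.6 to -61.8, and -74.3 points with an interval from -83.5 to -57.7. Over the genome, 106 windows were lower and 70 higher in Treg in both pairs, where independent lists would share 0.305 and 0.197. These expected numbers take every window as equally likely to be called. Calls depend on read depth and level, so the excess may be overstated. The PBS pair alone gave 518 lower and 361 higher windows, and the OX40L-JAG1 pair 185 and 172. Of the shared windows, 87 of the lower and 53 of the higher lay at a gene. With a minimum of 10 reads, 41 windows were lower and 43 higher in both pairs, and with all read counts divided by 3 these were 16 and 5.

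The other genes ranked lowest in Treg were called in both pairs by the rule that named them. Zfp609, a zinc finger gene, stood at 91.7% in PBS Teff and 22.3% in PBS Treg, and at 84.7% and 24.4% in the OX40L-JAG1 pair. Atxn7l1 differed by -64.4 and -60.4 points in the PBS and OX40L-JAG1 pair, Phtf2 by -56.9 and -67.8 points, and the flank of Sdhaf1 by -53.1 and -54.7 points. A single window at chromosome 3, 69009001 to 69010000, belongs to Smc4, to the microRNA genes Mir15b and Mir16-2 within it, and to the flank of Ift80. It stood at 58.2% and 6.06% in the PBS pair and at 51.8% and 1.82% in the OX40L-JAG1 pair. Morrbid, a long noncoding RNA gene, was lower in Treg by -46.2 and -48.9 points. It was also lower after OX40L-JAG1, by -27.2 points in Teff and -29.9 points in Treg, so that its level ran from 90.3% in PBS Teff to 14.2% in OX40L-JAG1 Treg.

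Genes higher in Treg were led by Emb, which differed by 44.9 points in the PBS pair and 46.2 points in the OX40L-JAG1 pair. Several encode regulators of T cells. Satb1, a chromatin organiser, differed by 44.9 and 44.6 points in the PBS and OX40L-JAG1 pair, and Tcf7, which encodes the transcription factor TCF-1 of naive and memory T cells, by 34.7 and 38.1 points. Themis, which acts in thymocyte selection, differed by 31.1 and 41.2 points. Pced1b, Rgs3 and Cabcoco1 differed by 53.0, 39.3 and 39.5 points in the PBS pair and by 62.0, 38.0 and 49.8 points in the OX40L-JAG1 pair. A window in Ggt5 and the flank of Ggt1 differed by 34.4 and 30.3 points.

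**Figure D3:**
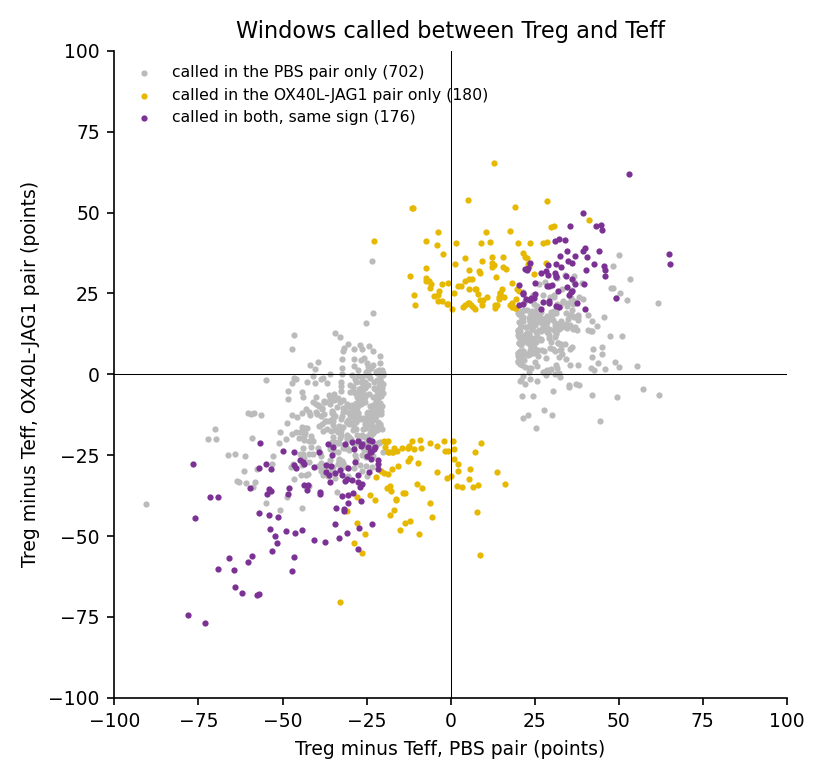
Windows called between Treg and Teff. The horizontal axis gives Treg minus Teff in the PBS pair and the vertical axis in the OX40L-JAG1 pair, in percentage points, and each point is a window. Purple points were called in the same direction in both pairs, 106 lower and 70 higher. Grey points, 702, were called in the PBS pair only, and 1 window called in opposite directions is not drawn.

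Some Treg signature genes held windows with less methylation in Treg. Of 24 measured, 10 held a lower window in the PBS pair, 6 in the OX40L-JAG1 pair and 6 in both, where random lists held a mean of 0.0731 in both and 0% of them held as many. The 6 genes were Foxp3, Ikzf2, Ikzf4, Il2ra, Tigit and Cd83. Il2ra encodes CD25, the marker the sort was made on. It stood at 93.0% and 62.3% in the PBS pair and at 95.7% and 46.6% in the OX40L-JAG1 pair. Of 8 windows of Tigit, an inhibitory receptor, the window at chromosome 16, 43628001, stood at 94.5% and 25.4% in the PBS pair and at 53.5% and 15.4% in the OX40L-JAG1 pair, and it was lower after OX40L-JAG1 in Teff by -41.0 points. The Tigit locus differed by -6.56 and -6.54 points in these pairs, and by -3.48 points after OX40L-JAG1 in Teff. Cd83, a surface protein of activated lymphocytes, stood at 91.3% and 69.6% in the PBS pair and at 71.3% and 42.0% in the OX40L-JAG1 pair, and its treatment difference was called in both cell types. Gpr83, Tnfrsf9, Rgs1 and Entpd1 were lower in Treg in the PBS pair, by -42.6, -46.6, -41.0 and -20.8 points, and were not called in the OX40L-JAG1 pair, where they differed by -16.7, -1.14, -20.5 and 0.129 points. None of these 4 was among the windows with a called interaction. Over the list, the median locus difference was -11.2 points in the PBS pair and -4.28 points in the OX40L-JAG1 pair, against medians of -0.286 and 0.512 for random lists. Single loci ran from -46.9 to 11.5 points in the PBS pair and from -40.0 to 8.53 points in the OX40L-JAG1 pair, so some were higher in Treg. With a minimum of 10 reads, 3 genes of the list held a window lower in both pairs.

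Some naive and conventional T cell genes held windows with more methylation in Treg. Locus differences of the list ran from -12.0 to 31.9 points in the PBS pair and from -5.27 to 20.4 points in the OX40L-JAG1 pair. Of 20 measured, 5 held a window higher in Treg in both pairs, namely Bach2, Lef1, Satb1, Tcf7 and Themis, against a mean of 0.0650 in random lists, and 0 held a lower one. With a minimum of 10 reads, 2 genes held a window higher in both pairs, and with all read counts divided by 3, 1 gene. Lef1, a transcription factor partnered with TCF-1, had a window at chromosome 3, 131123001 to 131124000, that stood at 37.3% and 86.5% in the PBS pair and at 65.7% and 89.2% in the OX40L-JAG1 pair. Bach2, a repressor of effector differentiation, stood at 31.5% and 62.9% and at 44.3% and 78.5% in a window at chromosome 4, 32303001. Dapl1 was called higher in Treg in the OX40L-JAG1 pair, by 25.6 points. Of the effector and helper lineage genes, Maf and Irf4 held a window lower in Treg in the PBS pair, by -23.6 and, at the larger of its windows, -42.0 points. Batf, Gata3 and Rora held one in the OX40L-JAG1 pair, by -26.3, -23.0 and -49.4 points. None of the 22 did in both.

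Markers of other cells gave few differences between Treg and Teff. The 10 B cell genes and the 9 measured CD8 T and NK cell genes held 0 called windows in any comparison. Matched random lists held few as well. In the PBS pair their means were 0.199 lower and 0.116 higher genes for the B cell list. For the CD8 T and NK cell list they were 0.0518 and 0.0332, so these counts of 0 do not set the lists apart. Of 12 measured myeloid genes, Spi1, which encodes the transcription factor PU.1, was higher in Treg in both pairs, by 36.2 and 29.5 points at chromosome 2, 91088001. Pan T cell genes with a called window in the PBS pair included Cd3e, higher in Treg by 23.9 points, and Ubash3a, lower by -25.2 points. Over the 15 pan T cell genes, the median locus difference was 3.50 points in the PBS pair and 5.39 points in the OX40L-JAG1 pair. Random lists had medians of -0.288 and 0.521 points, and the naive list 1.19 and 2.65 points. More methylation in Treg was therefore not particular to the naive list. Single pan T cell loci ran from -15.3 to 18.9 points and from -11.6 to 16.8 points, and 1 gene held a window higher in both pairs. In the OX40 and NF-kB list, Tank, which binds TRAF proteins, held a window lower in Treg in both pairs, by -23.5 and -46.4 points, and Nfkb1, Stat5a and Stat5b held one in the PBS pair. The Stat5a window is shared with Stat5b, which also held a window higher by 23.6 points. Of the checkpoint genes, Havcr2 and Tox were lower and Nr4a2 higher in the PBS pair, by -26.0, -32.1 and 31.2 points at their largest windows. In the PBS pair, 1 of 4 windows of Dnmt1 was higher by 52.4 points and 1 of 12 windows of the imprinted gene Inpp5f lower by -43.8 points, with locus differences of 3.50 and -6.27 points. Proliferation, Notch, housekeeping and germline genes held 0 called windows between Treg and Teff.

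OX40L-JAG1 Teff differed from PBS Teff in 1753 windows, 1476 lower and 277 higher. The genes ranked lowest after OX40L-JAG1 included Tnfaip3, which encodes the NF-kB inhibitor A20. Its window at chromosome 10, 19010001 to 19011000, stood at 84.4% of 32 reads in PBS Teff and differed by -64.4 points in OX40L-JAG1 Teff, from 30 reads, with an interval from -78.0 to -40.7. It stood at 12.2% in PBS Treg and 0% in OX40L-JAG1 Treg. The 26 reads of the latter allow up to 12.9% by the Wilson interval, which takes them as independent. They are summed over positions and may come from fewer DNA molecules. Ccp110, a centriole gene, differed by -67.9 points and Rad51b, a DNA repair gene, by -52.3 points. A window shared by Jmjd1c and the flank of Reep3 differed by -56.2 points. Among the genes ranked highest, Slc35d3 rose from 2.94% to 74.4%, Pdlim5 from 29.1% to 90.5% and Elmo1 from 8.82% to 65.3%. Rreb1 and Ugcg rose by 52.0 and 48.0 points, and both were also called higher in Treg, by 35.2 and 39.9 points. Centring the differences on their median left 969 lower and 352 higher windows, so that the lower share went from 84.2% to 73.4%. With all read counts divided by 3, 52 lower and 14 higher windows were called.

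Some effector list genes held windows with less methylation, and some naive list genes windows with more, in the OX40L-JAG1 Teff library. Of 22 effector and helper lineage genes, 6 held a lower window and 0 a higher one, where random lists held a mean of 0.631 lower and 0% held as many. Prdm1, which encodes the effector regulator Blimp-1, was lower by -48.0 points with an interval from -55.9 to -39.4, in a window beside the gene at chromosome 10, 44432001 to 44433000. Irf4 was lower by -45.3 points, Maf by -29.8 points, Tbx21, which encodes T-bet, by -23.6 points, and Batf and Rora by -23.0 points each. The median locus difference of the list was -3.90 points, at the 8.45 percentile of random lists, and loci without a called window went both ways, such as Bcl6 at 10.8 points and Cxcr5 at -10.3 points. Of 20 naive and conventional T cell genes, 5 held a higher window, among them Bach2, Lef1, Satb1 and Tcf7, against a mean of 0.287 in random lists, and 2 a lower one. Bach2 rose by 33.6 points, Lef1 by 37.5 points, Satb1 by 27.2 points and Tcf7 by 22.8 points at their largest windows. Stat4 and Themis were lower, by -28.8 and -30.9 points at their largest windows. The median locus difference of the naive list was 0.347 points, against -2.80 points for random lists. With a minimum of 10 reads, 2 effector list genes held a lower window and 1 naive list gene a higher one. With all read counts divided by 3, these counts were 2 and 1.

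**Figure D4:**
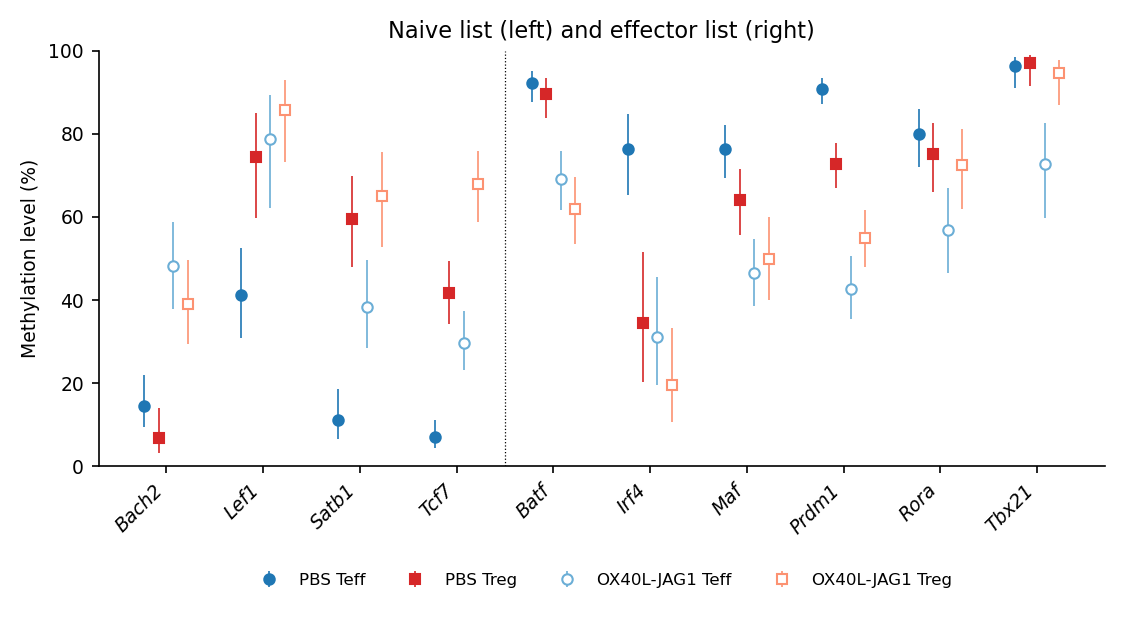
Methylation level in percent of the window with the largest called treatment difference in Teff, for the 4 naive list genes that held a window higher after OX40L-JAG1 and a window, not always the one drawn, higher in Treg in the PBS pair, and for the 6 effector list genes that fell. Points are the 4 libraries and bars are 95% Wilson intervals. Tcf7 stands at 7.0% in PBS Teff and 29.7% in OX40L-JAG1 Teff, and Prdm1 at 90.7% and 42.8%.

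Genes of the OX40 and NF-kB list held called windows both ways in Teff. Of 24 OX40 and NF-kB genes, 5 held a lower window, namely Bcl2, Nfkb1, Stat5a, Stat5b and Tank, where random lists held a mean of 0.732 and 0.09% of them as many. Stat5a and Stat5b share a lower window but count as separate genes. Random lists seldom hold such neighbours, so the excess may be overstated. The median locus difference of the list was -2.08 points against -2.55 points for random lists, at their 75.4 percentile. Bcl2, an inhibitor of apoptosis, was lower by -29.5 points in 1 of its 12 windows, while its locus differed by 0.681 points. The largest locus differences of the list in Teff were at Tnfrsf4, which encodes OX40, at 77.2% of 123 reads in PBS Teff and 38.2% of 102 reads in OX40L-JAG1 Teff, and at Nfkbia, at 61.0% of 123 reads and 38.5% of 122 reads. These loci held 0 windows with enough positions, so the differences of -39.0 and -22.5 points were not tested. Nfkb1 was lower by -29.7 points, Tank by -29.0 points, and the window shared by Stat5a and Stat5b by -24.4 points. Bcl2l1 and, at other windows, Stat5b were higher, by 28.3 and 40.5 points. Of 21 measured Notch pathway genes, Notch1 held a higher window beside the gene, at 5.26% in PBS Teff and 29.6% in OX40L-JAG1 Teff, and 0 held a lower one. Checkpoint genes Havcr2 and Tox were lower by -32.3 and -50.0 points. Single genes of other lists were Cd28 and Cd3e, lower by -31.5 and higher by 23.9 points, Ccnd3, higher by 21.3 points, Mbd2, lower by -32.2 points, the flank of Polr2a, lower by -36.0 points, and the germline gene Mael, lower by -31.5 points. Imprinted genes held 0 called windows in Teff.

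OX40L-JAG1 Treg differed from PBS Treg in 316 windows, 255 lower and 61 higher. Sox6 fell from 88.0% to 32.5%, a difference of -55.5 points with an interval from -69.5 to -36.0. Ext1, Igf2bp2 and the flank of Arrb1 were lower by -46.9, -49.2 and -45.0 points. Gpr55, a lipid receptor, fell from 52.8% to 14.5%, and it fell by 38.0 points in Teff as well. Among genes that rose, Epb41l2 went from 13.5% to 64.3%. Il2rg, the common cytokine receptor chain, was higher by 43.5 points. Dnah2 and the flank of P2rx4 rose by 31.3 and 39.5 points. Of the naive list, Bach2, Satb1 and Tcf7 were higher, by 32.3, 27.7 and 26.2 points, and Stat4 was lower by -28.9 points. Of the effector list, Batf and Maf were lower by -31.2 and -20.1 points. Tox, Tank, Mael and the imprinted gene Peg3 were lower by -24.8, -40.5, -27.0 and -22.6 points, and a window of Ikzf2 by -20.3 points. Notch, proliferation, housekeeping and DNA methylation genes held 0 called windows. With all read counts divided by 3, 1 lower and 0 higher windows were called. A limit of 50 reads per position, added after the data were examined, left 266618 of the 314531 windows. Of these, 80 were called lower and 22 higher in Treg, against 887 and 182 in Teff.

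The treatment differences of Teff and Treg overlapped. In both cell types 51 windows were lower, where independent lists would share 1.20, and 18 were higher, where they would share 0.0537. Of the 1476 windows lower in Teff, 81.4% were also below 0 in Treg, against 67.6% of all windows, with a median of -8.01 points. These comparisons share no library, but the labels do not say whether both cell types came from the same mice. The expected numbers take no account of shared animals or batches, nor of windows that differ in read depth. The interaction test called 34 windows, in 24 of which the difference in Treg lay above that in Teff. The Prdm1 window stood at 90.7% and 42.8% in PBS and OX40L-JAG1 Teff, and at 72.7% and 54.9% in Treg. With all read counts divided by 3, 1 interaction window was called.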

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

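The tests of bisulfite conversion, of Treg cells among Teff and of effector-like cells, the form in which movements were compared, and the checks on split read counts were chosen after the results were seen. The interaction test marked 34 windows whose response to OX40L-JAG1 differed between Treg and Teff. Among named and listed genes, the response of Treg minus that of Teff was 30.2 points at Prdm1, -68.5 points at Pdlim5, 21.5 points at a window of Rgs3 other than the one described above, and -26.2 points at Peg3. Positions covered in a single pair, outside the main comparisons, held further Foxp3 windows. At chromosome X, 7584001 to 7585000, Treg minus Teff was -50.7 points in the PBS pair, from 58 and 76 reads, and -51.2 points in the OX40L-JAG1 pair, from 68 and 75 reads. In the PBS pair, the window at 7594001 gave -34.3 points and the window at 7574001, beside the gene, 24.5 points.

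Methylation lay lower over the genome in both OX40L-JAG1 libraries. Incomplete conversion differed by at most 0.0152 points at mitochondrial cytosines, so incomplete conversion, as far as mitochondrial DNA shows it, does not account for the shift. These cytosines were almost unmethylated in all libraries and cannot show over-conversion of methylated cytosines. At positions with at most 50 reads the shift was still -2.92 points or beyond in both cell types, so piled-up reads do not account for it. Repeats with ordinary read numbers were not told apart. Among windows at 80% or more in the PBS library of the other cell type, the relative loss was at least 1.83 times as large in the fifth with the fewest CpG positions as in the fifth with the most, which argues against a uniform loss of methylated calls. The loss was larger in the gene-poorest than in the gene-richest megabases by -1.64 points in Teff and -1.70 points in Treg. This difference had the same sign within windows with a like number of listed positions. More cell divisions may give such a pattern, but it was read from gene density and not from replication timing. With 1 library per group, a difference between animals, sorts or library batches stays open, and so does an effect of the agents.

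Windows were lower in OX40L-JAG1 Teff than in PBS Teff. At 25 Treg signature windows lower in Treg in both pairs, a median of 2.74% of the gap to Treg was closed, and at the 31 lower in the PBS pair, whatever the other pair, 3.63%, but 19 of the 25 and 20 of the 31 lie in Ikzf2, which closed 1.38% and 1.22%. The 6 windows of the other genes closed 11.1% and the 81 windows outside the list 24.4%, and of the 11 windows of the other genes lower in the PBS pair, 6 closed over 20%, with a median of 41.8%. Cells with the low Ikzf2 levels of the sorted Treg would close the gap there too, which argues against them as the cause, while Treg-like cells that stay methylated at Ikzf2 are left open. After centring, 65.7% of the lower windows were still called, so an equal shift in every window is not their whole cause. Centring moved the difference required by the median and left the test itself unchanged. The loss was uneven over the genome, and subtracting a single median cannot tell an uneven shift from local changes. More effector-like cells among the sorted Teff may be a candidate explanation, since 0% of random lists held as many genes with a lower window as the effector list. However, a change within the same cells would look alike, and the random lists were not limited to genes active in T cells.

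Fewer windows differed between Treg and Teff in the OX40L-JAG1 pair than in the PBS pair, 357 against 879. At equal depth the PBS pair still called 2.39 times as many, which argues against read depth. At the 702 windows called in the PBS pair only, Teff moved towards Treg by a median of 17.6 points and Treg moved towards Teff by -0.920 points, a difference of 18.5 points, each less its genome-wide median. Choosing windows on the PBS libraries by itself moves values back. Windows were therefore also chosen on a random part of each window's summed read counts and measured on the rest. There the movements were 16.0 points for Teff and -3.93 points for Treg at 310 windows. The 33 windows called in the OX40L-JAG1 pair only gave -0.426 points for Teff and 9.58 points for Treg from OX40L-JAG1 to PBS. Counts from the same read or its duplicates can fall in both parts, so the split cannot remove the effect of the choice. The 702 and 310 windows were chosen as not called in the OX40L-JAG1 pair, which largely sets a net approach there. At 358 windows chosen in the same split on the PBS pair alone, the movements were 15.4 points for Teff and -4.04 points for Treg. An OX40L-JAG1 Teff library nearer to Treg at these windows restates the lower count, and gives no cause for it. Ikzf2 windows lower in the PBS pair closed a median of 1.22% of the gap to Treg, and those of other Treg signature genes 41.8%. The choice of windows stays open as a part of these movements. With 1 library per group, an unusual PBS Teff library would give the same values.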

How the results depend on the processing

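Alternatives named here as added, at most 50 reads per position and coverage in the compared pair, were chosen after the data were examined. The planned coverage minimum of 1 read was not run because the table lists no count below 5, and promoter values were not computed because the gene table gives no strand. Counts are given in the order lower and higher in Treg in both pairs, lower and higher in Teff after OX40L-JAG1, lower and higher in Treg after OX40L-JAG1, with main values of 106, 70, 1476, 277, 255 and 61, and 34 for the interaction.

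With a minimum of 10 reads, 73995 windows were left, and the counts were 41, 43, 202, 66, 77 and 22, and 24 for the interaction. At a difference of 30 points they were 55, 30, 333, 101, 80 and 23, and 24 for the interaction. With reads divided by 3 they were 16, 5, 52, 14, 1 and 0, and 1 for the interaction. Both settings with fewer reads and the higher threshold lower counts by construction. At equal depth the counts were 71, 41, 491, 108, 79 and 18, and 12 for the interaction. Windows of 500 bp gave 82, 65, 820, 233, 157 and 42, and 35 for the interaction, from 185349 windows. Centring gave 107, 68, 969, 352, 192 and 68, and 34 for the interaction. It moved the lower share from 84.2% to 73.4% in Teff. Autosomes alone gave 105, 71, 1383, 268, 232 and 58, and 32 for the interaction. The added limit of 50 reads gave 69, 38, 887, 182, 80 and 22, and 19 for the interaction, from 266618 windows. Added pairwise coverage gave 3459 lower and 543 higher in Teff, from 959320 windows. The counts in both pairs were then 119 and 73, and those in Treg after OX40L-JAG1 266 and 65.

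limma over all 4 libraries called 0 windows lower and 0 higher in Treg, and 0 genes of the Treg signature and naive lists. It recovered 0% of simulated drops of 50 points, so its count says nothing of stability. At an unadjusted p under 0.05 with 20 points it gave 1067 windows for cell type and 1018 for treatment, and 130 or 97 for the remaining split of the libraries, depending on the block.

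At equal depth, Treg signature genes lower in both pairs numbered 6 and naive genes higher in Teff 5, as in the main values, and naive genes higher in both pairs and effector genes lower in Teff numbered 4 and 4. List counts fell further under other settings, and not every change is listed. Treg signature genes lower in both pairs went from 6 to 3 with a minimum of 10 reads and to 3 with reads divided by 3, and naive genes higher in both pairs from 5 to 2 and to 1. Effector genes lower in Teff went from 6 to 2 with a minimum of 10 reads, to 2 at 30 points and to 2 with reads divided by 3. Naive genes higher in Teff went from 5 to 1 with a minimum of 10 reads, to 2 with windows of 500 bp, to 2 at 30 points, to 1 with reads divided by 3 and to 3 with the added limit of 50 reads.

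Library levels moved by less than 1 point. PBS Teff with a minimum of 10 reads, at 85.20%, and OX40L-JAG1 Treg at equal depth, at 82.17%, stayed within their counting intervals, and the values that follow did not. PBS Teff was 85.23% as mean of position levels, 85.14% at equal depth, 85.29% on autosomes and 85.42% with the added limit of 50 reads. PBS Treg was 84.92% with a minimum of 10 reads, 84.96% as mean of levels, 84.87% at equal depth, 84.98% on autosomes and 85.13% with the limit. OX40L-JAG1 Teff was 81.70%, 81.48%, 81.67%, 81.68% and 81.64% in the same order. OX40L-JAG1 Treg was 82.28% with a minimum of 10 reads, 82.02% as mean of levels, 82.21% on autosomes and 82.14% with the limit. The shift between treatments ran from -3.79 to -3.47 points in Teff and from -2.99 to -2.65 points in Treg over these settings. The cause of changes not set by construction was not tested. With a minimum of 10 reads, lower windows no longer outnumbered higher ones between Treg and Teff, at 41 and 43 in both pairs and 134 and 147 in the PBS pair, against 518 and 361 there. Simulated drops of 30 points, above the threshold of 20, were recovered in 44% to 76% of windows, so real differences of that size may be missed.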

Other observations

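The comparisons of this part were chosen after the results were seen. The 277 windows higher in OX40L-JAG1 Teff had a median of 31.0% in PBS Teff and 60.9% in OX40L-JAG1 Teff, and the 1476 lower ones of 88.3% and 62.0%. Of the higher windows in Teff, 105 were also higher in PBS Treg than in PBS Teff, and of the lower windows 196 were also lower there. These comparisons share the PBS Teff library, so part of that overlap comes from its chance values.

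Interaction windows outside the fixed lists, named after their values were seen, included Ptk2b at 91.9%, 73.6%, 52.4% and 65.0% in PBS Teff, PBS Treg, OX40L-JAG1 Teff and OX40L-JAG1 Treg. Pdcd1lg2, which encodes a ligand of the inhibitory receptor PD-1, stood at 90.6% in PBS Teff and 32.2% in PBS Treg, and fell by 50.6 points in Teff after OX40L-JAG1. Epg5 stood at 91.0%, 14.4%, 54.0% and 26.3%, and Cblb, a ubiquitin ligase that restrains T cell activation, at 78.6%, 32.1%, 43.1% and 55.2%.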
